A study of Mus musculus with 2 samples.

How the data were processed

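Cells from the thymus of WT and Mgl2DTR mice were profiled as 1 pool of droplets with the 10x Chromium 3′ kit, and a hashtag library was made beside the gene expression library, per the labels. Both GEO samples, 1 for gene expression and 1 for hashtags, hold cells of both genotypes. Reads were processed with Cell Ranger 6.0.0 and Seurat 4.0.4 on the mouse build mm10, per the submitters' processing notes, and the gene annotation is not given in the sources used here. The deposited gene tables hold raw counts, whole UMIs per gene and cell, for 20451 genes and 28926 cells, and the deposited hashtag tables hold raw UMI counts of 3 hashtags for the same cells. A deposited annotation gives for each cell the hashtag call and a score, the margin between its strongest and second hashtag. Its UMI totals were checked against the gene tables and were equal for every cell. Genotype was taken from the hashtag call and not from the table a cell was in. Of the annotation, 6 columns were not used, and no deposited cell types were used here, although the design had assumed that cell types and perhaps animals would be named.

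The analysed cells were those with a single genotype hashtag: 11586 WT cells, 40.1% of all, and 7433 Mgl2DTR cells, 25.7%. Cells with a pair of hashtags (9829, 34.0%) and with none (78, 0.27%) were left out of every comparison. Median genes per cell were 2295 in WT and 2146 in Mgl2DTR, and median mitochondrial shares were 1.97% and 1.89%. No further filter on depth or mitochondrial share was applied in the main results.

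Cells were clustered with scripts in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without Mgl2, and 30 principal components and 20 nearest neighbours were given to the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9, resolution 1, seed 1). Figures were drawn with matplotlib 3.10.9. A marker counted for a cluster when its CPM was at least 2 times that of the other cells, with 10 CPM added to both, and 20% of the cluster's cells held it. A cluster was named by the fixed marker list with the largest share of such genes, needed at least 3, and stayed unnamed when 60% of another lineage's list counted as well, when more of another lineage's markers than of its own were among its top 10 genes, or when its cells were shallow and none of its own markers led. Of 34 clusters, 27 were named and 7 stayed unnamed, and the names end in "-like" because they come from markers alone. Clustering was repeated without the IL-4/13 genes and at resolution 0.5.

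Same-genotype doublets cannot be seen by hashtag. Cells with both genotype hashtags (4755) led to an expected 3706 such doublets among WT cells (32.0%) and 1525 among Mgl2DTR cells (20.5%). The cells with both hashtags had a median of 7299 gene UMIs, against 7820 in WT and 6930 in Mgl2DTR single-hashtag cells, where droplets of a pair of cells should hold more. They were deeper than the single-hashtag cells of both genotypes in 11 of 25 clusters and shallower in 9, so they need not all be doublets, and the expected numbers and the calls built on them are uncertain. A cell was called a doublet when at least 12 of its 50 nearest neighbours were known doublets, which called 3175 WT cells (27.4%) and 2159 Mgl2DTR cells (29.05%) and held for 80.0% of the known doublets themselves. Known doublets were here all 9829 cells with a pair of hashtags. Of these, 5074 carried the third hashtag, whose meaning the labels leave open. The cut was chosen to bring the number of calls near the expected total. As a share of neighbours it lies below the 34.0% of all cells that were known doublets. A called cell therefore need not lie among more known doublets than the cells as a whole. Called cells stayed in the main results and were left out in an alternative.

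Shares of cells carry exact Clopper-Pearson intervals. For each of 26 clusters with at least 50 cells per genotype, UMIs were summed per genotype and scaled to the total of the cluster, CPM received exact Poisson intervals, and ratios received exact conditional intervals. A gene was measured in a cluster with at least 50 summed counts. With 1 library per genotype no test was made, and a gene was called higher or lower by size only, at a ratio of at least 1.5 either way with the whole interval on that side of 1. A gene with 0 counts in 1 genotype was set against 3 counts. With no replicates, edgeR and DESeq2 were not used.

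Before the data were examined, lists were fixed for IL-4/13 response, type I and III interferon response, dendritic cell activation and homing, class II and class I presentation, NF-kB and inflammation, handling stress and immediate early response, cell cycle, efferocytosis and lipid handling, chemokines, glycolysis and hypoxia, mitochondrially encoded genes, ribosomal proteins, sex-linked genes and cell type markers, as were the groups, the tests and most alternatives. A list with at least 5 measured members was summarised by its median log2 ratio, with 0.5 counts added where a gene had 0 counts, and by the percentile of that median among 10000 random lists of the same size matched on level. Named genes are Mgl2, the list members of largest ratio, and the 5 highest and 5 lowest genes per cluster by the interval bound nearest to 1, leaving out sex-linked, ribosomal, mitochondrial, immunoglobulin, T cell receptor and haemoglobin genes. The rule names 337 values over the 10 clusters described, of which the text gives a selection made after the values were seen, and the stability of all 337 is counted. Gene positions come from an mm10 annotation, GENCODE vM21.

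To compare shares of cells with an Mgl2 UMI at equal depth, each cell was thinned to 2000 UMIs at random and shallower cells were left out. The comparison was tested on simulated data in which 200 genes per cluster were changed by known folds among the 3454 to 10035 genes of each cluster. Both simulated libraries were Poisson draws from the WT profile of the cluster, without spread between cells or animals. Coverage near 95% followed from this setting, and the shares below hold for counting error only. Intervals covered the true ratio for 95.4 to 96.8% of genes, calls were right for 100% of 4-fold, 78.6 to 100% of 2-fold and 27.8 to 55.7% of 1.5-fold changes, and 0.854 to 4.44% of unchanged genes were called. A true 1.5-fold change lies at the size threshold itself, so these shares do not measure what depth allows. In the same simulation a list of 15 raised genes reached percentile 100 in each of the 10 clusters, and 1 list of 15 unchanged genes per cluster lay anywhere from percentile 4 (cluster 7) to 95.7 (cluster 14) and 99.9 (cluster 3), so a percentile near 0 or 100 alone does not show that a list changed. Alternatives were another scaling (median of ratios, or each cell scaled to the same total), other count minimums, thinning, filters on mitochondrial share, on UMIs of other types' markers (2 or more) and on called doublets, other denominators for shares, and list means in place of medians.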

Results

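Single-cell transcriptomes were recorded from the thymus of 7-week-old wild-type mice (WT) and of Mgl2DTR_eGFP mice (Mgl2DTR), whose name joins Mgl2 to the diphtheria toxin receptor and a green fluorescent protein. Mgl2 encodes CD301b, a galactose-binding lectin of type 2 dendritic cells and some macrophages. Toxin kills mouse cells that carry the receptor. The labels give 500 ng of toxin for Mgl2DTR mice and 48 h of exposure, and leave open whether WT mice received it. Thymus was digested with collagenase, T-lineage cells carrying CD90.2 were depleted on magnets, and live cells stained for CD11c and CD11b, surface proteins of dendritic and myeloid cells, were sorted. Both genotypes were run as 1 pool of droplets, with an oligonucleotide hashtag on the cells of each genotype. A single genotype hashtag was carried by 11586 WT cells (116719748 UMIs, median 7820 per cell) and 7433 Mgl2DTR cells (71521759 UMIs, median 6930 per cell). No animals were named, so each genotype was 1 library and the differences between genotypes had no replicate check. Levels are given in CPM, the summed UMIs of a gene scaled to the total of the same cells. A range after a value is its exact 95% interval, which covers counting error only, and ratios are Mgl2DTR over WT.

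The first question was whether Mgl2, which checks the genotype labels, was lower in the Mgl2DTR library. Mgl2 (ENSMUSG00000040950.13; mm10, chromosome 11, 70130329 to 70137550, plus strand, a protein-coding gene) stood at 109.2 CPM (107.3 to 111.1) in WT cells and 17.9 CPM (17.0 to 18.9) in Mgl2DTR cells. In the class of type 2 conventional dendritic cells (cDC2-like, Sirpa+) it was 690.6 CPM (675.6 to 705.9) in WT and 245.4 CPM (226.1 to 265.9) in Mgl2DTR. In macrophage-like cluster 4 the levels were 134.7 CPM (126.7 to 143.2) and 26.5 CPM (21.7 to 32.1). With each cell thinned to 2000 UMIs, an Mgl2 UMI was found in 47.1% of 1033 WT and 21.5% of 237 Mgl2DTR cDC2-like cells (intervals 44.0 to 50.1% and 16.5 to 27.3%). The same share over all cells deep enough was 9.30% of 10208 WT cells and 2.33% of 6303 Mgl2DTR cells. Unthinned, the shares were 66.6% and 40.6% in cDC2-like cells, at median depths of 10253 and 9883 UMIs, and 15.9% and 6.14% over all cells. In T cell-like cells, which should lack the gene, 0.680% of WT and 0.932% of Mgl2DTR cells held a UMI after thinning and 1.38% and 1.39% before it, at median depths of 3124 and 3634.5 UMIs. Mgl2 was lower in 13 of the 14 clusters in which it was measured, with a median ratio of 0.276. The Mgl2 transcripts that remained in Mgl2DTR cDC2-like cells lay above the share in T cell-like cells.

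**Figure D1:**
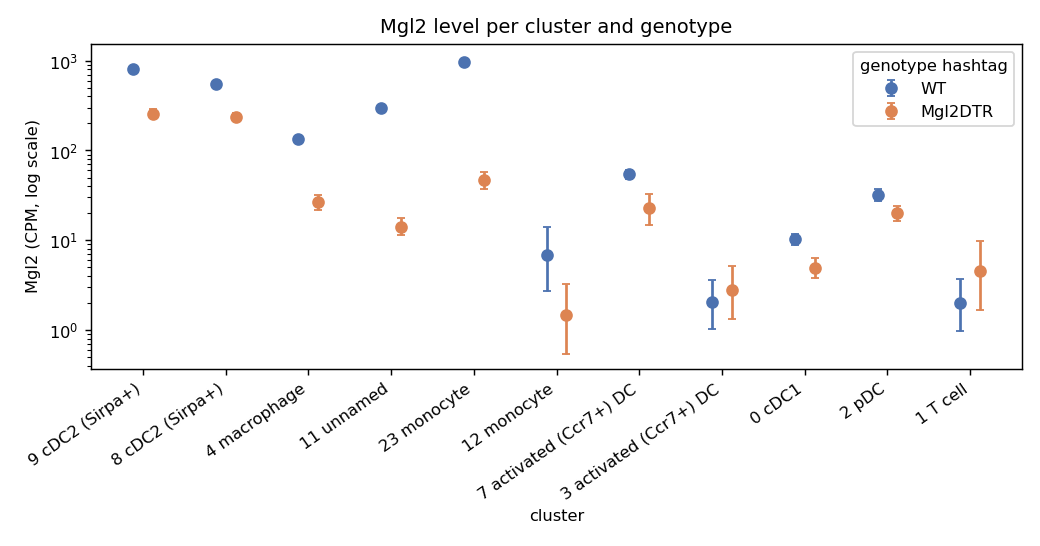
Mgl2 level in CPM (log axis) for WT and Mgl2DTR cells of 11 clusters, with exact 95% Poisson intervals as error bars, which cover counting error only. In cDC2-like cluster 9 the level was 810.2 CPM in WT and 257.1 CPM in Mgl2DTR cells, and in the unnamed cluster 11 it was 300.1 and 14.2 CPM.

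The second question was how the make-up of the sorted cells differed. cDC2-like cells made up 9.24% of WT cells (1070 cells, 8.71 to 9.78%) and 3.28% of Mgl2DTR cells (244 cells, 2.89 to 3.71%), a ratio of 0.355 (0.308 to 0.409). Both of their clusters were smaller, at ratios of 0.312 for cluster 9 (0.251 to 0.384) and 0.400 for cluster 8 (0.329 to 0.484). Type 1 conventional dendritic cells (cDC1-like), specialised in cross-presentation, differed less, with 20.5% in WT, 18.4% in Mgl2DTR and a ratio of 0.898 (0.839 to 0.960). The 2 classes are not defined alike, since cDC1-like includes cycling clusters 5 and 10 and cDC2-like includes no cycling cluster. The unnamed cycling cluster 11, with Mgl2 at 300.1 CPM in WT and 14.2 CPM in Mgl2DTR, was in neither class. Its ratio of shares was 1.42 (1.21 to 1.68). Activated, Ccr7+ dendritic cells made up 13.9% and 12.5% (0.905, 0.834 to 0.982), and within that class cluster 3 was larger (1.19) and cluster 7 smaller (0.485) in Mgl2DTR. Plasmacytoid dendritic cells (pDC-like) were at 9.52% in WT and 13.3% in Mgl2DTR (1.40, 1.28 to 1.52).

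Cells of the neutrophil-like and monocyte-like classes took a larger part of the Mgl2DTR library. Neutrophil-like cells made up 3.61% of WT and 13.2% of Mgl2DTR cells, a ratio of 3.65 (3.26 to 4.11), with cluster 6 at 8.34 (6.87 to 10.2), cluster 30 at 5.14 (3.31 to 8.22) and cluster 14 at 1.38 (1.15 to 1.65). Monocyte-like cells were at 1.98% and 7.79%, a ratio of 3.94 (3.38 to 4.61), with cluster 12 at 3.377 (2.815 to 4.065) and cluster 23 at 5.725 (4.23 to 7.86). All 55 WT cells of cluster 23 were called doublets. They were unlike its Mgl2DTR cells, with Mgl2 at 963.1 CPM against 46.9 CPM. B cell-like cells had the ratio 2.34 (1.96 to 2.80) and natural killer or innate lymphoid-like cells 1.42 (1.22 to 1.66), with their clusters going opposite ways (2.405 for cluster 19, 1.935 to 2.996, and 0.749 for cluster 21, 0.582 to 0.957). Macrophage-like cells were at 6.78% and 5.79% (0.854, 0.757 to 0.962). T cell or thymocyte-like cells, which the magnetic depletion should remove, made up 18.8% of WT and 6.75% of Mgl2DTR cells, a ratio of 0.359 (0.325 to 0.396). Unnamed clusters held 10.8% and 10.4% of cells. Shares of 1 library sum to the whole, so a larger share of 1 type lowers the others, and the depletion and the sort can set them too. With dendritic cell types alone as the denominator, cDC1-like and activated cells had ratios of 1.00 and 1.01, and cDC2-like cells 0.397.

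**Figure D2:**
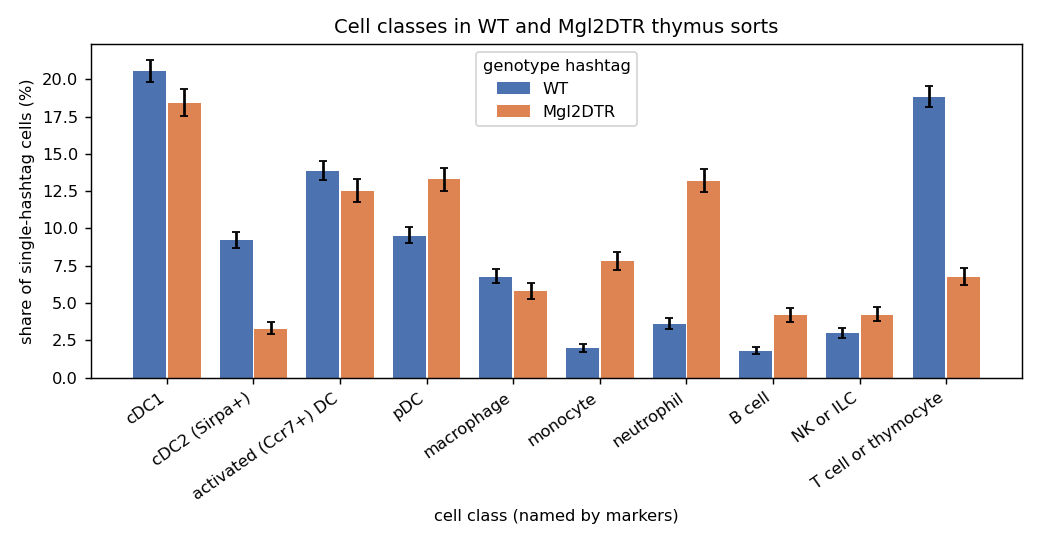
Share of cells (percent, from 0) in each of 10 cell classes for WT (11586 cells) and Mgl2DTR (7433 cells), with exact 95% binomial intervals as error bars, which cover counting error only. The cDC2-like bars stand at 9.24% and 3.28%, and the neutrophil-like bars at 3.61% and 13.2%.

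The series title concerns type 2 cytokines and Sirpa+ dendritic cells, so the levels of 24 genes of the interleukin-4 and interleukin-13 (IL-4/13) response were compared across WT clusters. Their summed level was highest among the 8 clusters plotted in cDC2-like cluster 9 (3970.9 CPM, 3922 to 4020.2), followed by activated clusters 7 (3696 CPM) and 3 (3184.3 CPM) and cDC2-like cluster 8 (2356.4 CPM). Monocyte-like cluster 12, pDC-like cluster 2 and macrophage-like cluster 4 were at 1268.3, 932.2 and 866.3 CPM, and cDC1-like cluster 0 at 411.9 CPM (402.9 to 421.1), close to the 392.5 CPM of T cell-like cluster 1. Of the clusters not plotted, neutrophil-like cluster 14 reached 3343.6 CPM, of which Chil3 gave 2935.4, and the 55 WT cells of monocyte-like cluster 23, all of them called doublets, reached 12315 CPM (12011.7 to 12624.1), of which the resistin-like gene Retnla gave 8358.4. The genes behind these sums differed between clusters. In cluster 9 the C-type lectin Cd209d alone gave 2016.2 CPM, with the transcription factors Klf4 at 311.8 CPM (42.8 in cluster 0) and Irf4 at 101.0 CPM (1.66 in cluster 0). Activated clusters held the chemokine Ccl22, at 1788.5 CPM in cluster 3 and 1628.8 CPM in cluster 7 against 12.6 CPM in cluster 0. Ccl17 was at 778.3 CPM in activated cluster 7, 411.5 CPM in cDC2-like cluster 8, 238.5 CPM in activated cluster 3 and 4.67 CPM in cluster 0. The receptor gene Il4ra was at 73.7 CPM in cluster 3 and 5.35 CPM in cluster 0, and Il13ra1 at 61.1 CPM in cluster 9 and 23.3 CPM in cluster 0. In cDC2-like clusters 9 and 8, Il4ra was at 11.8 and 18.4 CPM, below pDC-like cluster 2 (22.4) and T cell-like cluster 1 (55.8). Clusters were partly built on these genes, so no test between clusters was made.

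**Figure D3:**
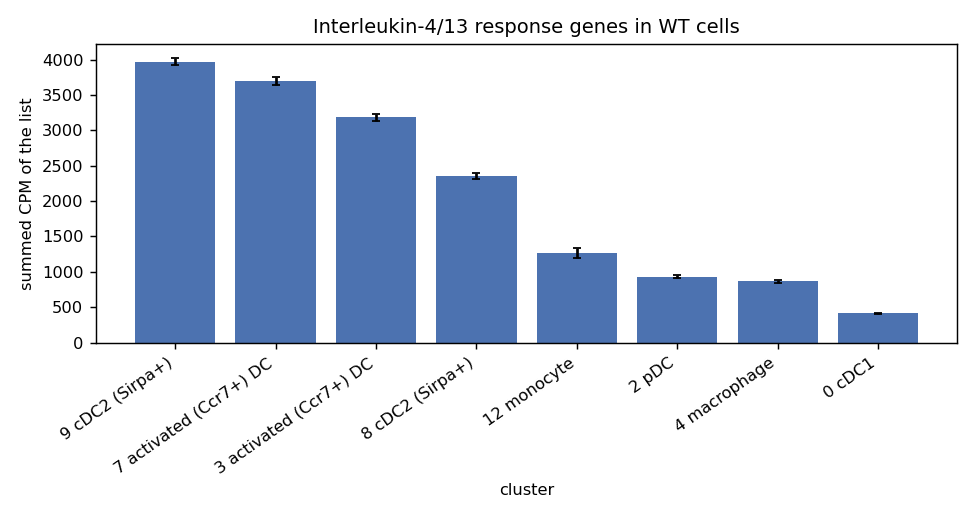
Summed CPM of the 24 IL-4/13 response genes in WT cells of 8 clusters, with exact 95% Poisson intervals as error bars, which cover counting error only. Bars run from 411.9 CPM in cDC1-like cluster 0 to 3970.9 CPM in cDC2-like cluster 9.

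Within cDC2-like cluster 9 (540 WT and 108 Mgl2DTR cells), the IL-4/13 response, activation and class II lists had medians below 0 in Mgl2DTR, with members going both ways. Of 18 IL-4/13 genes measured, 8 were lower and 2 higher, with a median log2 ratio of -0.51, at percentile 0 among 10000 random lists matched on level, as a description of these libraries. Mgl2 was at a ratio of 0.317 (0.281 to 0.358), the ribonuclease gene Ear2 at 0.0617 (282 WT counts and 3 Mgl2DTR counts, 0.0126 to 0.182) and Ccl17 at 0.0883 (197 and 3 counts, 0.0181 to 0.262). Mgl2, the gene that marks cells for the toxin, is itself on the IL-4/13 list. The list median cannot tell a lower response from the loss of Mgl2-carrying cells. Of 24 genes of dendritic cell activation and homing, 10 were lower and 1 higher (median -0.49). The class II genes H2-Eb1 (0.568, 0.548 to 0.588), H2-Ab1 (0.572) and H2-Aa (0.611, 0.593 to 0.629) were lower, while the protease gene Lgmn was higher (1.75), and the median of 13 class II genes, 3 of them lower and 1 higher, was -0.25. The cytokine gene Il6 (105 WT counts) and the calcium-binding protein gene Tesc (123 WT counts) had 0 Mgl2DTR counts. Set against 3 counts they were 6.04-fold and 7.07-fold lower, and their ratios had upper bounds of 0.207 and 0.177. Higher in Mgl2DTR were the protease inhibitor Slpi (14.4 and 84.2 CPM, ratio 5.86, 4.34 to 7.92), the growth factor receptor Kdr (3.84, 2.98 to 4.93) and the complement protein properdin, Cfp (148.0 and 477.7 CPM, ratio 3.23, 2.89 to 3.60). Chemokine genes (10 of 20 lower, 3 higher, median -0.56), cell cycle genes (5 of 16 lower, median -0.53) and NF-kB genes (3 of 12 lower, 1 higher, median -0.23) also had medians below 0. T cell markers had a median of -2.20 in the same cells, with 8 of 10 lower and 1 higher. With at least 200 counts per member the IL-4/13 median was -1.26. Called doublets made up 28.3% of the WT and 11.1% of the Mgl2DTR cells of cluster 9. Without cells called doublets, the activation median was -0.015, that of interferon response genes turned from -0.24 to 0.54, and Ccl17 was at a ratio of 0.358. The 3 Mgl2DTR counts of Ear2 came from 1 cell, and Lgmn was at 2.97 after thinning.

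In cDC2-like cluster 8 (530 and 136 cells) the IL-4/13 list was split, with 5 of 20 genes higher, 5 lower and a median of -0.05 at percentile 10.8. Ear2 (380.6 and 121.7 CPM, ratio 0.320, 0.271 to 0.375) and Ccl17 (411.5 and 247.1 CPM, ratio 0.6004, 0.533 to 0.674) were lower. The lectin gene Clec10a, next to Mgl2 on chromosome 11, was higher (111.2 and 278.4 CPM, ratio 2.504, 2.19 to 2.86), and so was the mannose receptor gene Mrc1 (2.53, 1.82 to 3.49). Outside the lists, the interferon-induced membrane protein gene Ifitm1 was at 17.3 CPM in WT and 344.1 CPM in Mgl2DTR (ratio 19.9, 15.9 to 25.2). The lectin gene Cd209e (0.0627, 0.0169 to 0.163), the transcription elongation factor gene Tcea3 (0.134, 0.0758 to 0.219) and the macrophage elastase Mmp12 (240.8 and 59.0 CPM, ratio 0.245, 0.193 to 0.308) were lower. NF-kB genes went both ways (3 of 13 higher, 3 lower), with a median of 0.09 and a mean of -0.21, and class II genes had a median of 0.01 and a mean of -0.04. T cell markers were lower in 6 of 7 (median -1.65). Without cells that held UMIs of other types' markers, Mrc1 was at 7.44, Ccl17 at 0.398, Cd209e at 0.155 and Mmp12 at 0.406.

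In activated dendritic cell clusters 3 and 7 the NF-kB and inflammatory list had medians above 0. In cluster 3 (810 and 619 cells) 12 of 15 members were higher and 0 lower, with a median of 0.94 at percentile 100, and in cluster 7 (521 and 162 cells) 7 of 13 were higher and 1 lower, with a median of 0.64 at percentile 100. The neutrophil-attracting chemokine Cxcl2 was at 46.5 CPM in WT and 674.5 CPM in Mgl2DTR cells of cluster 3 (ratio 14.5, 12.7 to 16.6), and Ccl3 at 4.81 and 19.5 CPM (4.06, 2.55 to 6.63). The costimulatory genes Cd80 (1.74, 1.51 to 2.01) and Tnfrsf4 (1.69, 1.57 to 1.82) were higher in cluster 3. In cluster 7, Tnfrsf4 (222.6 and 458.9 CPM, ratio 2.06, 1.85 to 2.29), the cytokine gene Il12b (34.1 and 154.7 CPM, ratio 4.54, 3.65 to 5.65), Tnf (2.63, 1.52 to 4.49) and Nfkb1 (1.51, 1.27 to 1.80) were higher. In cluster 7 the efferocytosis and lipid list had a median of 0.62 (4 of 7 higher, 0 lower), the higher ones including the cholesterol exporter Abcg1 (1.97, 1.71 to 2.27) and the bridging protein Mfge8 (1.90, 1.56 to 2.29). Its IL-4/13 list had a median of 0.31 and a mean of -0.30, with 1 of 13 higher and 3 lower, including Ear2 (46.0 and 5.04 CPM, ratio 0.110, 0.0398 to 0.243). Mmp12 had 144 WT counts and 0 Mgl2DTR counts in cluster 7, and 47.9% of the WT counts came from 1 cell. Set against 3 counts it was 12.3-fold lower, and its ratio had an upper bound of 0.101. In cluster 3 the IL-4/13 median was 0.13 (2 of 13 higher, 1 lower). Neutrophil markers were higher in cluster 3 (8 of 8, median 1.72), and T cell markers in cluster 7 had a median of -1.30 (5 of 9 lower).

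Several of these values changed with the cells kept or the scaling. Cxcl2 UMIs in cluster 3 came from 116 of 619 Mgl2DTR cells, and the ratio was 4.84 without cells holding other types' markers and 7.25 with each cell scaled to the same total. The chemokine Cxcl1, at 10.7 and 117.4 CPM, had a ratio of 0.815 without cells holding other types' markers, where the main ratio was 10.9. The cytokine gene Il1b, at 88.3 and 331.4 CPM in cluster 3 (3.75, 3.37 to 4.18), had a ratio of 0.657 without cells called doublets, and the itaconate-forming enzyme gene Acod1 likewise turned from 15.25 to 0.701. In cluster 7 the Il12b ratio was 1.35 and that of Ear2 0.362 without cells holding other types' markers, and Tnfrsf4 was at 1.37 after thinning. Called doublets made up a larger part of the Mgl2DTR cells, at 33.8% against 20.6% of WT cells in cluster 3. In cluster 7 they made up 27.2% of Mgl2DTR and 19.2% of WT cells. The NF-kB medians without cells called doublets were 0.33 in cluster 3 and 0.41 in cluster 7.

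**Figure D4:**
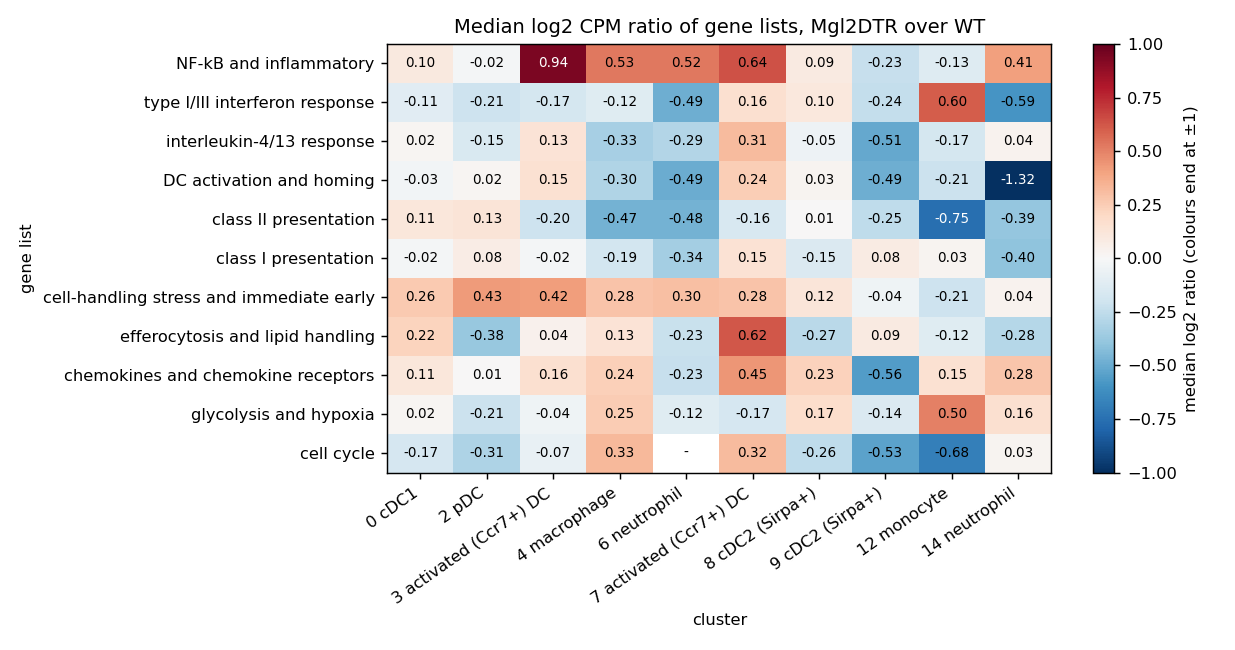
Median log2 CPM ratio, Mgl2DTR against WT, of 11 fixed gene lists in 10 clusters, as a colour scale that ends at 1 and -1. The NF-kB row reaches 0.94 in activated cluster 3, and the class II row -0.75 in monocyte-like cluster 12.

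In cDC1-like cluster 0 (1406 and 855 cells) the IL-4/13, NF-kB and class II lists had medians near 0, and single genes passed the size rule. The antiviral membrane protein gene Ifitm2 was at 38.8 CPM in WT and 122.4 CPM in Mgl2DTR (3.16, 2.89 to 3.45). Il1b (65.2 and 117.7 CPM, ratio 1.81, 1.67 to 1.95), Il12b (6.54 and 14.9 CPM, ratio 2.28, 1.80 to 2.89) and the stress-responsive transcription factor Atf3 (1.73, 1.64 to 1.83) were higher. The splicing-related gene Rsrp1 (0.495, 0.464 to 0.527) and the annexin partner S100a10 (0.481, 0.436 to 0.529) were lower. The medians were 0.02 for IL-4/13 (2 of 17 higher, 2 lower), 0.10 for NF-kB and 0.11 for class II genes, with T cell markers at -0.49. In pDC-like cluster 2 (874 and 807 cells) 5 of 17 genes of handling stress and the immediate early response were higher and 0 lower (median 0.43), among them Fosb (48.8 and 124.1 CPM, ratio 2.54, 2.20 to 2.94) and Jun (1.84, 1.75 to 1.94). The transcription factor Mef2a was higher there (2.00, 1.83 to 2.18) and the antiviral gene Rsad2 lower (0.452, 0.282 to 0.707), with medians of -0.21 for interferon (3 of 15 lower, 0 higher) and -0.15 for IL-4/13 genes.

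Class II lists had medians below 0 in macrophage-like cluster 4 and monocyte-like cluster 12. In cluster 4 (669 and 351 cells) 5 of 13 class II genes were lower and 0 higher (median -0.47, percentile 0), with H2-Eb1 at 8661.7 and 4649.2 CPM (0.537, 0.528 to 0.546) and the invariant chain Cd74 at 24845.6 and 14351.9 CPM (0.578, 0.572 to 0.583). Of 14 NF-kB genes 7 were higher and 0 lower (median 0.53), including Cxcl2 (4.25, 3.88 to 4.65), Il1b (448.8 and 874.7 CPM, ratio 1.95, 1.86 to 2.04) and the inflammasome gene Nlrp3 (1.96, 1.58 to 2.42), and the monocyte attractant Ccl2 was at 3.45 (2.99 to 3.98). The IL-4/13 list had a median of -0.33 (6 of 20 lower, 2 higher, percentile 0): Mgl2 (0.197, 0.159 to 0.240) and Ear2 (0.249, 0.194 to 0.318) were lower, and the chitinase-like gene Chil3 (20.9 and 108.0 CPM, ratio 5.18, 4.31 to 6.24) and the eosinophil attractant Ccl24 (59.5 and 286.9 CPM, ratio 4.82, 4.32 to 5.38) higher. Here as well the list median cannot tell a lower response from the loss of Mgl2-carrying cells. Ifitm1 (13.8, 10.1 to 19.2) and the matrix proteoglycan Vcan, a monocyte marker (1.80 and 24.7 CPM, ratio 13.7, 7.80 to 26.0), were higher, and the class I-like gene H2-M2 was lower (369.6 and 87.3 CPM, ratio 0.236, 0.211 to 0.264). Cell cycle genes were higher in 6 of 18 and lower in 0 (median 0.33), as for the helicase subunit Mcm5 (2.02, 1.65 to 2.48). In the same cells neutrophil markers had a median of 0.85 and cDC2 markers one of -0.58 (4 of 9 lower, 3 higher), with Cd209a at 135 WT and 10 Mgl2DTR counts (0.145, 0.0680 to 0.275). Without cells called doublets, Cxcl2 was at 6.54, and Cd209a was at 0.483 without cells holding other types' markers, of which it is 1 itself.

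In monocyte-like cluster 12 (174 and 377 cells; median depths of 4740.5 and 8933 UMIs) 7 of 12 class II genes were lower and 0 higher (median -0.75, percentile 0), with H2-Aa at 1178.4 and 473.3 CPM (0.402, 0.374 to 0.432) and Cd74 at 0.436. Interferon response genes were higher in 8 of 18 and lower in 0 (median 0.60, percentile 100), among them Isg15 (151.8 and 296.2 CPM, ratio 1.95, 1.65 to 2.32), Oasl2 (1.98, 1.46 to 2.73) and Oas1a (1.95, 1.35 to 2.92). Glycolysis and hypoxia genes had a median of 0.50 (4 of 11 higher, 1 lower), with Aldoa at 1.58 and Pgk1 at 1.53 (1.31 to 1.80), and cell cycle genes one of -0.68 (11 of 18 lower, 0 higher). Ifitm1 was at 19.3 and 866.6 CPM (44.8, 29.0 to 73.5), the alarmin S100a9 at 1624 and 18159.5 CPM (11.2, 10.7 to 11.7) and Il4ra at a ratio of 2.59 (1.67 to 4.21). The prostaglandin-degrading enzyme Hpgd (279.4 and 34.0 CPM, ratio 0.122, 0.0987 to 0.150) and the lipid carrier Apoe (868.1 and 210.1 CPM, ratio 0.242, 0.220 to 0.266) were lower. NF-kB genes went both ways in cluster 12 (3 of 12 higher, 2 lower), with a median of -0.13 and a mean of 0.33. IL-4/13 genes had a median of -0.17 and a mean of 0.06 (2 of 9 higher, 2 lower), and neutrophil markers a median of 1.33 (5 of 9 higher). Ifitm1 was at 22.4 with each cell scaled to the same total, Apoe at 0.160 without cells called doublets, and the class II median then at -1.25.

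Genes also differed within neutrophil-like clusters. In cluster 6 (122 and 653 cells) 7 of 15 NF-kB genes were higher and 1 lower (median 0.52), with Cxcl2 at 4214.1 and 19867.5 CPM (4.71, 4.43 to 5.02) and Cxcl3 at 60.8 and 815.7 CPM (13.4, 8.10 to 24.1), while the interferon response list had a median of -0.49 (6 of 16 lower, 0 higher), with Ifit2 among the lower (166.1 and 25.6 CPM, ratio 0.154, 0.0938 to 0.250). Class I genes had a median of -0.34, with H2-K1 at 0.594 and B2m at 0.640. In cluster 14 (269 and 238 cells; median depths of 6647 and 13141 UMIs) Cxcl2 (302.6 and 1185.5 CPM, ratio 3.92, 3.64 to 4.22) and Ccl4 (3.01, 2.66 to 3.41) were higher, 10 of 19 interferon response genes were lower and 1 higher (median -0.59), and the cystatin-like gene Cstdc5 was at 48.8 and 847.1 CPM (17.4, 14.6 to 20.8). Markers of activated dendritic cells (10 of 10 lower, median -2.09) and T cells (median -1.47) were lower in cluster 14 as well. The median over all genes was -0.17 in cluster 6, so its ratios stand relative to that shift. Cluster 6 was shallow, with median depths of 1763 and 1707 UMIs. Its WT counts of Cxcl3 were 15 in 6 cells, and those of Ifit2 were 41 in 15 cells, with 31.7% in 1 cell. Thinning left out 77 of 122 WT and 434 of 653 Mgl2DTR cells of cluster 6. It moved Cxcl3 there to 68.8, a value that rests on few WT counts. Scaling each cell to the same total moved Cstdc5 in cluster 14 to 6.03.

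Over all single-hashtag cells, which mix levels with the shares of cell types, NF-kB genes had a median of 0.68 (9 of 16 higher, 0 lower, percentile 100), handling stress genes 0.36 (4 of 17 higher), chemokine genes 0.40 (11 of 25 higher, 1 lower) and glycolysis genes 0.26 (2 of 12 higher). Medians were -0.39 for dendritic cell activation (4 of 24 lower, 0 higher), -0.30 for class II, -0.16 for class I and -0.15 for interferon response genes, with 0 genes past the size rule in the last 3 lists. The IL-4/13 median was -0.12 (5 of 24 higher, 6 lower) with a mean of 0.01. Cell cycle and efferocytosis genes were both at 0.11, mitochondrially encoded genes at 0.03 and ribosomal protein genes at -0.03. The medians of cell type markers were: neutrophil 1.42 (10 of 10 higher), monocyte 0.97, B cell 0.95, non-classical monocyte 0.45, pDC 0.28, plasma cell 0.22, cDC1 -0.03, natural killer or innate lymphoid -0.19 (where the share was larger), thymic epithelium -0.29, macrophage -0.37, cDC2 -0.43, activated dendritic cell -0.57 and T cell -1.25 (10 of 13 lower). Fibroblast markers had a median of 2.10 at low levels, with summed CPM of 11.4 and 44.5. Among sex-linked genes, Xist was at 0.257 and 0.210 CPM and Tsix at 6 and 7 counts, while Ddx3y was at 46.3 and 59.3 CPM, Eif2s3y at 19.97 and 33.2, Kdm5d at 11.5 and 11.8, and Uty at 11.5 and 12.7.

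Across clusters, a pair of genes outside the lists differed in nearly every cell type. Hsph1, a heat shock protein of the Hsp110 family (chromosome 5, 149614287 to 149636376), was higher in 21 of 24 clusters measured, with a median ratio of 1.88 and a range from 1.484 to 3.48. Rsrp1 (chromosome 4, 134923592 to 134927671) was lower in 23 of 26 clusters and below 1 in all 26, with a median of 0.571 and a range from 0.379 to 0.696. Both were singled out after their values were seen. Ifitm1 was higher in 17 of 22 clusters (median 6.25), Cxcl2 in 16 of 22 (3.96) and Ccl2 in 10 of 10 (3.28), while the lectin gene Cd209a was lower in 13 of 15 (0.338). These calls rest on summed UMIs and do not show that most cells of a cluster differed. Ifitm1 was held by 25 of 295 Mgl2DTR cells of cluster 5, with 52.1% of its UMIs in 1 cell. Cxcl2 was held by 31 of 162 Mgl2DTR cells of cluster 7, with 46.05% in 1 cell, but by 608 of 653 in neutrophil-like cluster 6.

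**Figure D5:**
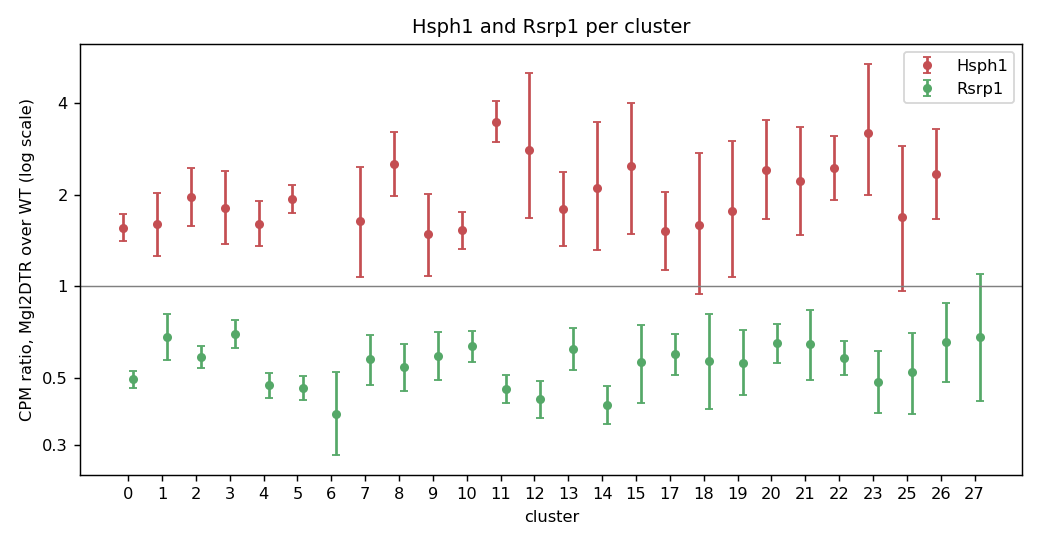
CPM ratio of Hsph1 and Rsrp1, Mgl2DTR against WT, in each cluster with at least 50 cells per genotype (log axis; exact 95% counting intervals as error bars). Hsph1 lies between 1.484 and 3.48 and Rsrp1 between 0.379 and 0.696.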

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

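The tests of free T cell RNA, of neutrophil RNA at the rate of cluster 6, of chromosome 11, both tests of doublets behind Hsph1 and Rsrp1, and of cell handling were chosen only after the result was seen, and so was the rule that the whole interval must lie past a bound in the test of doublets with T cells.

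The hashtag data held signal outside the comparisons. A total of 5074 cells carried a genotype hashtag together with the third hashtag, whose name in the hashtag tables (IL4RaKO) differs from that in the cell annotation. The annotation calls them hashtag pairs and not cells of 1 genotype. The third hashtag came with the WT hashtag in 2312 cells (7.99%) and with the Mgl2DTR hashtag in 2762 (9.55%). Its median was 880 and 1007.5 UMIs in these, against 22 in single-hashtag cells of either genotype. Cells with both genotype hashtags numbered 4755 (16.4%, 16.0 to 16.9%), with medians of 1201 WT and 927 Mgl2DTR hashtag UMIs, where single-hashtag cells held 1424 and 1234 of their own. Cells with the third hashtag beside the WT or the Mgl2DTR hashtag had median depths of 15764 and 10862.5 gene UMIs. The median depth of cells with both genotype hashtags was 7299, against 7820 and 6930 in WT and Mgl2DTR single-hashtag cells. Within clusters it lay above that of single-hashtag cells of both genotypes in 11 of 25, such as cluster 14 (15318 against 6647 and 13141) and cluster 5 (27252 against 22739 and 21124), below both in 9, such as cluster 0 (6205.5 against 13607 and 13712), and between them in 5. Markers of more than 1 lineage were found in 70.0% of cells with both genotype hashtags, in 83.6% and 72.8% of those with the third hashtag, and in 50.9% of WT and 43.5% of Mgl2DTR single-hashtag cells. The hashtag tables hold 31621002 UMIs over 15604 cells and 27390782 UMIs over 13322 cells. By count, the third hashtag was the strongest in 1095 cells of the table named for Mgl2DTR and in 0 of the other.

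The T cell marker list had medians below 0 in Mgl2DTR within dendritic cell-like clusters 0, 3, 7, 8 and 9, from -0.19 to -2.17 when 0.5 counts were added to every gene. That of cluster 3, at -0.19, was close to 0. Because the droplets were shared, free T cell RNA released after pooling would by itself give both genotypes the same CPM. The median over the 5 clusters was -1.26 (-1.50 to -0.63), outside the band around 0 set for this cause. That median is the pattern itself, so this test could not come out otherwise, and no conclusion is drawn from it. Cluster 3 alone lay inside the band around 0 set for this cause. RNA taken up before pooling is not covered. Doublets with T cells may account for part of the lower T cell markers. Without called doublets the median over the 5 clusters was -0.98, past the bound of -0.94 set against this cause. Its interval (-1.29 to -0.44) reaches past that bound and the bound set for the cause (-0.63), so doublets cannot be told apart from other causes. A difference between genotypes in how T cells bind or load dendritic cells was not tested and stays open.

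Cxcl2 was higher in Mgl2DTR cells of activated cluster 3. The neutrophil genes S100a8 and S100a9 were higher in these cells too, at 680.9 CPM in WT and 2317.5 CPM in Mgl2DTR. Neutrophil RNA matching that excess would bring 6.48% of the Cxcl2 excess (upper bound 7.23%) at the Cxcl2 rate of neutrophil-like clusters 6 and 14 pooled, below the bound set against this cause, and 46.3% (upper bound 51.9%) at the rate of cluster 6 alone. These clusters differ in Cxcl2 (19867.5 CPM in cluster 6 and 1185.5 CPM in cluster 14 of Mgl2DTR), and the pooled rate assumes a mix that the tables do not show for these cells, so neutrophil RNA cannot be told apart from a difference in the cells themselves. Without cells holding other types' markers, S100a8 among them, the Cxcl2 ratio fell from 14.5 to 4.84. A Cxcl2 UMI was held by 18.7% of the Mgl2DTR cells (15.7 to 22.0%), and 1 cell held 18.7% of the UMIs. A few cells taking most of the counts therefore cannot be told apart from a broader difference, since the share lies between the bounds set for the test. Toxin-induced cell death or the genotype could also be behind the level, and this was not tested.

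Hsph1 was higher and Rsrp1 lower in Mgl2DTR in most clusters. A chromosome 11 segment kept from the targeted strain does not explain them as neighbours of Mgl2, since 0 of the genes lie on that chromosome. By fold, the tables also argue against the cells called doublets as the cause. By count, 72.7% of the calls of both genes remained without these cells (32 of 44), short of the bound set against this cause. Of the 12 calls that ended, 7 were in clusters left with fewer than 50 cells of a genotype, so the folds were taken to decide. In the clusters that kept 50 of each, the median log2 change of both genes, with the sign of Rsrp1 turned, was 0.834 with all cells and 0.843 without called doublets (0.759 to 0.976). The median ratio of Hsph1 went from 1.795 to 1.946 (above 1 in 17 of 17 clusters), and that of Rsrp1 from 0.568 to 0.586 (below 1 in 18 of 18). Doublets that were not called stay open, and the calls themselves are uncertain. A difference between the genotypes in cell handling before they were pooled may contribute, and the labels do not say whether they were digested and sorted together: the fixed handling stress list had a median above 0 in 84.6% of clusters (22 of 26). The heat-responsive genes Hspa8 (higher in 9 of 26 clusters and above 1 in 26, median 1.44) and Dnaja1 (higher in 10 of 25 and above 1 in 24, median 1.44) went the same way as Hsph1. Hspa8 is itself on the handling stress list, which holds other heat shock genes too, so these values are not independent support. The heat-responsive and cold-responsive genes given here were chosen after their values were seen. Of the cold-responsive genes, Cirbp was lower in 3 of 24 clusters and higher in 0 (median 0.939, from 0.404 to 1.351), and Rbm3 passed the size rule in 0 of 26 (median 1.05). A response to toxin or genotype in every cell type stays open as untested.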

How the results depend on the processing

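All values without called doublets, for genes, lists and Mgl2, the other random draw for Mgl2, and both repeats of the clustering were chosen after seeing the data. The lower cDC2-like share held under all 6 alternatives, at ratios from 0.320 to 0.397. Counting dendritic cell types alone gave 1.00 for cDC1-like, 1.01 for activated and 1.56 for pDC-like cells, and leaving out B, T, NK and stromal cells gave 0.809, 0.816 and 1.26. Without called doublets the ratios were 0.808 for activated, 5.11 for monocyte-like and 4.22 for neutrophil-like cells, and with cells of at least 2000 UMIs and under 5% mitochondrial share that of neutrophil-like cells was 2.75. Over the 7 dendritic and myeloid classes, 29 alternative ratios stayed within the main interval and 10 did not.

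The share of all cells with an Mgl2 UMI had a ratio of 0.251 when thinned to 2000 UMIs, 0.247 in another random draw, 0.201 when thinned to 1000, 0.385 unthinned and 0.297 without called doublets. In cDC2-like cells the ratio was 0.457, and 0.530 in the other draw. In macrophage-like cluster 4 it was 0.203, 0.163 in the other draw and 0.0875 when thinned to 1000 UMIs. Of the 100 genes named by size, 63 were named again with no filter beyond 1 count and 41 with 200 summed counts, by construction of the filter. In cluster 3, Cxcl1 turned to 0.815 without cells holding other types' markers, and Acod1 and Il1b turned to 0.701 and 0.657 without called doublets. Over all 337 named values, 34 reversed in at least 1 setting, in 47 of 2017 alternative values: 20 without called doublets, 20 without cells holding other types' markers, 5 after thinning, 2 with per-cell scaling, and 0 with median-of-ratios scaling or without cells over 5% mitochondrial. In the 10 clusters described, called doublets made up 5.20 to 40.7% and cells holding other types' markers 6.89 to 78.9% of the cells per genotype.

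List means were 1.36, 0.80 and 1.03 for NF-kB in clusters 3, 7 and 4, -0.68 for interferon in cluster 9 and -0.30 for IL-4/13 in cluster 7. With at least 200 counts per member, NF-kB in cluster 3 was 0.74 and IL-4/13 in cluster 9 was -1.26. Without called doublets, NF-kB was 0.33, 0.41 and 0.74 in clusters 3, 7 and 4, class II in cluster 12 was -1.25, activation in cluster 9 was -0.015 and interferon in cluster 9 reversed to 0.54. In all, 47 list values stayed within the main interval, 12 moved out of it and 1 reversed. With each WT cell scaled to the same total, the IL-4/13 sums of clusters 0, 2, 3, 4, 8 and 12 were 432.2, 903.4, 3077.4, 892.7, 2227.2 and 1403.6 CPM. The cause of these differences was not tested.

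No paired analysis was possible because no animals were named and each genotype was 1 library. For the same reason an edgeR test on cell counts, DESeq2 as a tool, leaving out each animal and a replicate block were not run. Deposited cell types were not used, so the planned clustering became the main result.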

Other observations

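No tests are reported here, and the genes and clusters were singled out after their values were seen.

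Monocyte-like cluster 23 held 55 WT and 202 Mgl2DTR cells of unlike content, and the median over all its genes was 0.12. Its WT cells carried Mgl2 at 963.1 CPM (46.9 CPM in Mgl2DTR). The resistin-like gene Retnla, a type 2 response gene, was at 8358.4 CPM in WT and 10.9 CPM in Mgl2DTR. The resident macrophage genes Cd209f and Timd4 had 112 and 55 WT counts and 0 Mgl2DTR counts. Set against 3 counts they were 129-fold and 63.2-fold lower. The Mgl2DTR cells of cluster 23 carried arginase, Arg1, with 2679 counts in 137 of 202 cells and 0 WT counts (259-fold higher against 3 counts). Vcan had 1286 Mgl2DTR counts and 0 WT counts (124-fold higher against 3 counts). Cxcl2 was at 2376 CPM in Mgl2DTR against 82.7 CPM in WT. Class II genes were lower there (10 of 13, 2 higher, median -1.74) and glycolysis genes higher (10 of 11, 0 lower, median 1.78), with macrophage markers at -2.27, monocyte markers at 2.35 and neutrophil markers at 2.72. All 55 WT cells and 28.2% of the Mgl2DTR cells were called doublets, so the WT profile is known only from cells that neighbour doublets.

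The unnamed cycling cluster 11 (309 and 282 cells) also differed in Mgl2, at 300.1 CPM in WT and 14.2 CPM in Mgl2DTR. Only 118 WT and 112 Mgl2DTR cells of cluster 11 were not called doublets. Ear2 was at 132.9 and 4.44 CPM there, Ifitm1 at 7.29 and 1494 CPM (ratio 205, 149 to 292), and the granule protease gene Prtn3, of early neutrophil precursors, at 3.15 and 215.2 CPM. The smallest ratio of shares was that of the Rag1+ thymocyte-like cluster 16, at 3.52% of WT and 0.242% of Mgl2DTR cells (0.0688), and the unnamed cluster 15, which mixes markers of activated dendritic cells and T cells, was at 3.37% and 0.700% (0.208). Over all single-hashtag cells Rag1, needed for antigen receptor rearrangement, was at 22.8 and 2.34 CPM, and Arg1 at 0.857 and 39.3 CPM (ratio 45.8, 37.5 to 56.5).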
